A study of Mus musculus with 17 samples.

How the data were processed

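Pol II ChIP-seq was measured in primary mouse embryonic fibroblasts of the C57Bl/6 background at day 3 after lentiviral infection with a hairpin against Rpap1 or a non-targeting hairpin. Per the labels, chromatin of 3 lines was pooled, and immunoprecipitated with an antibody to total Pol II or to Ser5P. The series has 17 samples: 5 ChIP-seq samples, of which 1 is input chromatin, and 12 RNA-seq samples from fibroblasts and from embryonic stem cells. The table analysed here has 8 value columns, promoter and gene body for each of 4 ChIP libraries. The RNA-seq samples and the input have no values in it and were not used here, so the planned RNA comparisons and input subtraction were not made.

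The deposited values are a signal, read here as base coverage, at the promoter and over the gene body per the column headers. Per the submitters' processing notes, FastQC, SAMtools 0.1.16, bedtools 2.23.0 and MACS2 2.0.10.20130712 were used with build GRCm38 (mm10). The aligner, read filters, promoter window, any correction for input and any scaling to a common depth are not given in the sources used here. All 144688 promoter values were whole multiples of a step of 0.721 within 0.0051, the same step in each library. The most common values above the lowest, at 41 and 81 steps, are those that 1 and 2 reads of 40 bases plus a step would give, so a read was taken as worth 29.6. The lowest promoter value, 0.72, was read as no coverage. The gene body floor depends on gene length. Read equivalents are approximate, and for gene bodies rest on RefSeq gene lengths.

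The table has 36230 rows, of which 58 exact repeats were dropped, leaving 36172 genes. Values were used as deposited. Per gene the log2 ratio of shRPAP1 over SCR was taken after adding the 5th percentile of all values (0.72 for promoters, 0.33 for gene bodies). A gene counted as measured with an antibody when it exceeded, in at least 1 of its 2 libraries, the 95th percentile of the 1799 background genes in that library. Genes were counted as lower or higher at a fold of 1.5. Intervals of single genes are exact 95% Clopper-Pearson intervals of the ratio of read equivalents. They cover counting error only. Intervals of a median over genes are 95% order-statistic intervals, which take genes as independent and cover no variation between libraries. Groups, the ratio, the filter, the 30 gene lists and most alternatives were fixed before the data were examined.

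A list with at least 5 measured members was described by the percentile of its median among 10000 random lists of the same size, drawn from measured genes in the same decile of mean signal. This describes these libraries and is not a test. Lists matched on gene length were drawn from the same decile of length in place of signal, so they do not hold signal constant. Level was ranked with the SCR library of the other antibody, since a ranking on the same library regresses to the mean. Gene lengths came from RefSeq on GRCm38.p6, with 1476 genes matched through an older symbol. They covered 88.6% and 87.7% of promoters measured with total Pol II and Ser5P, and 83.7% and 84.6% of gene bodies.

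The rule for named genes took Rpap1; in each region the 10 genes with the largest increase and the 10 with the largest decrease in the same direction with both antibodies, ranked by the smaller of the absolute ratios; and from each list the 2 highest and 2 lowest measured members. Predicted genes, receptors and mitochondrial genes were left out of the ranking. Of the 20 genes this ranking gave per region, 19 at promoters and 19 over gene bodies had no coverage in a library, so a ratio has no meaning for them. The promoters of Mast2 (145 and 203 in SCR with total Pol II and Ser5P) and Bahd1 (116 and 145) were at the floor in both shRPAP1 libraries, and that of Chchd10 was at the floor in both SCR libraries and held 174 and 232 in shRPAP1. The ranking was therefore repeated, after these values were seen, over genes above 2 times the background percentile in both libraries of each antibody (the stricter filter), and the text names those genes. Some genes that the rule gave are not reported here.

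Alternatives were the median of ratios set to 1, background genes set equal, the median background subtracted, pseudocounts 10 times smaller and larger, no filter, the stricter filter, and predicted names left out. Chosen after the data were seen were the mean background subtracted (alone, with the stricter filter, or for lists matched on the other antibody), protein-coding genes alone, and lists past the stricter filter. For promoter against gene body, no filter with genes ranked by the SCR promoter signal of the other antibody, also split by its gene body signal, was chosen then too. Of the background genes 1760 are receptors, so the settings that use them rest mainly on these. The steps were tested on simulated data: Poisson reads around the SCR signal, with a common factor of 0.5, background 1.6 times higher and 200 changed genes, 50 for each fold and direction. Over measured genes the common log2 change of -1 was returned as -0.98 and -0.99 at promoters with total Pol II and Ser5P. Over gene bodies it was returned as -0.56 and -0.65, so these medians understated it. Over gene bodies with total Pol II, the median log2 ratio, relative to the most occupied decile, of genes lowered a further 2-fold was -0.89 and of those raised 2-fold 0.92, with 92% and 100% counted; for 4-fold changes it was -1.53 and 1.87. At promoters with total Pol II, 68% of genes lowered 2-fold and 94% of those lowered 4-fold were counted. A list of 30 genes shifted by -0.5 lay at percentile 0 with either antibody, and 4.40% and 5.40% of 500 unshifted lists fell in the tails. Exact intervals held the true ratio for 97.2% and 97.0% of 500 promoters. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.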

Results

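RPAP1 is a protein that associates with RNA polymerase II (Pol II). The study depleted it in primary mouse embryonic fibroblasts with a lentiviral short hairpin (shRPAP1) and used a non-targeting hairpin (SCR) as the control. The values analysed here are ChIP-seq signal at the promoters and over the bodies of 36172 genes in 4 libraries, made at day 3 after infection from the chromatin of 3 pooled fibroblast lines. Total Pol II and Pol II phosphorylated at serine 5 of its C-terminal repeats (Ser5P), a mark of polymerase early in transcription, were each measured in 1 SCR and 1 shRPAP1 library. There are no replicates, so higher and lower refer to these libraries and not to the conditions, and no test between conditions is given. The RNA-seq samples of the series and the input chromatin are not analysed here. The free-text description of both shRPAP1 ChIP samples names the SCR control, while their titles, treatments and hairpins name the knockdown, and the groups follow the latter.

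Promoter signal was worth about 129646 reads in the total Pol II SCR library and 71311 in the shRPAP1 library. With Ser5P it was worth about 290769 and 156172 reads. No promoter coverage was listed for 46.7% of genes in SCR and 45.5% in shRPAP1 with total Pol II, and for 43.8% and 42.3% with Ser5P. Signal over genes taken as background was higher in the shRPAP1 libraries. Over 1799 genes expected to be silent in fibroblasts, 1760 of them olfactory and vomeronasal receptors, mean promoter signal was 8.03 in SCR and 14.0 in shRPAP1 with total Pol II, and 6.597 and 10.1 with Ser5P. Mean gene body signal of the same genes was 7.13 and 12.4 with total Pol II, and 5.82 and 9.99 with Ser5P. Without the receptors, the 39 other silent genes had promoter means 1.49 and 4.61 times higher with total Pol II and Ser5P, but gene body means 1.08 and 1.06 times higher, so over gene bodies a scaling that sets the background genes equal rests on the receptors.

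Rpap1, the targeted gene, had a promoter signal of 211 in SCR and 325 in shRPAP1 with total Pol II, worth about 7 and 11 reads (log2 ratio 0.62, 95% counting interval -0.85 to 2.26). With Ser5P its promoter signal was 886 and 541, worth about 31 and 19 reads (log2 ratio -0.71, interval -1.61 to 0.16). Its gene body held 14.3 in each total Pol II library, and 25.9 and 20.4 with Ser5P. These differences were within counting error, and their signs depended on the scaling: the total Pol II ratio was -0.18 with background genes set equal, and the Ser5P ratio 0.25 with the median of ratios set to 1. A hairpin acts on the messenger RNA, so Pol II on the gene does not check the depletion.

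The question for total Pol II was whether RPAP1 depletion changed its abundance on genes. Total Pol II as deposited was lower at most measured genes in the shRPAP1 library. In the most occupied decile of genes, ranked by Ser5P in SCR, it was 2.04-fold lower over gene bodies (median log2 ratio -1.03, 1387 genes) and 2.18-fold lower at promoters (-1.12, 1442 genes). Among the gene bodies with the largest differences, that of Tnc, which encodes the matrix glycoprotein tenascin C, fell from 564 to 111 (5.05-fold, log2 ratio -2.34, counting interval -2.44 to -2.25), and that of Tpm1, an actin-binding tropomyosin, from 1531 to 420 (log2 ratio -1.86, -1.957 to -1.77). Chac1, which degrades glutathione, was among the gene bodies ranked highest with both antibodies, at 92.9 and 122, but an increase was not detectable at this depth (log2 ratio 0.39, -0.35 to 1.16).

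Fibroblast and mesenchymal genes stood apart from genes of like signal over gene bodies. Of 40 genes, 34 were measured with total Pol II, 30 of them at least 1.5-fold lower and 0 higher. Their median log2 ratio was -1.31, against -0.86 for random lists of like signal, below each of 10000 such lists (percentile 0). Timp1, an inhibitor of matrix metalloproteinases, held 305 in SCR and 75.9 in shRPAP1 (log2 ratio -2.004, -2.59 to -1.47), and Lox, which crosslinks collagen, 1003 and 298 (-1.75, -1.91 to -1.60). Twist1, a transcription factor of mesenchyme, held 56.9 in each library, and the next smallest differences in the list were those of Cdh2, N-cadherin, at 47.9 and 33.6 (-0.51, -0.64 to -0.38), and Zeb2, a repressor of epithelial genes, at 70.5 and 48.8 (-0.53, -0.67 to -0.39). Among actin and SRF target genes, 26 of 27 were measured and 26 were at least 1.5-fold lower, with a median of -1.37 against -0.98 (percentile 0.02). Actg2, a smooth muscle actin, held 210 and 57.0 (-1.87, -2.16 to -1.61), and Actb, the cytoskeletal beta actin, 1829 and 779 (-1.23, -1.41 to -1.06).

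Immediate early, inflammatory, histone and Hox genes had lower total Pol II medians over gene bodies than random lists of like signal, but most of these differences depended on the setting. Of 27 measured immediate early genes 22 were at least 1.5-fold lower, with a median of -1.14 against -0.86 (percentile 0.57, but 15.5 with the mean background subtracted and 21.8 past a stricter filter). Nr4a1, an orphan nuclear receptor, held 207 and 58.4 (-1.82, -2.12 to -1.54), and Egr3, a zinc finger transcription factor, 59.3 and 4.05 (-3.77, -7.11 to -2.03). Of 20 measured NF-kB and inflammatory genes 15 were at least 1.5-fold lower (median -0.95 against -0.63, percentile 1.18). Ccl2, a chemokine that attracts monocytes, held 276 and 72.4 (-1.92, -3.02 to -1.03), whereas Tnfaip2 held 60.9 and 56.8 (-0.10, -0.56 to 0.38). Replication-dependent histone genes had 52 of 68 measured members at least 1.5-fold lower (median -1.23 against -0.94, percentile 0), but 12.7 with the mean background subtracted. Hist1h4c held 1592 and 409, worth only about 8 and 2 reads over its short body (-1.958, interval -5.27 to 0.33, not detectable at this depth). Hox genes had 14 of 18 measured members at least 1.5-fold lower (median -0.86 against -0.49, percentile 0.64, but 11.6 with lists matched on gene length). Hoxb4 held 87.8 and 18.7 (-2.21, -3.83 to -0.98).

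Interferon and antiviral genes differed less than genes of like signal in total Pol II. Over gene bodies 11 of 26 measured members were at least 1.5-fold lower and 1 higher, with a median of -0.46 against -0.78 (percentile 99.7, but 85.8 matched on gene length and 92.1 past the stricter filter; 0.095 with the median of ratios set to 1). Irf7, a transcription factor of the interferon response, held 166 and 79.5 (-1.06, -1.79 to -0.35), Stat2, which carries interferon signals, 147 and 81.03 (-0.85, -1.11 to -0.60), and Rsad2, an antiviral enzyme, 71.0 and 75.7 (0.09, -0.31 to 0.49). Genes of the unfolded protein and integrated stress response reached the 96.7th percentile (11 of 23 measured members lower and 1 higher, median -0.47 against -0.71), and the 98.9th with the mean background subtracted and lists matched on the other antibody. Xbp1, a transcription factor of the unfolded protein response, held 309 and 115 (-1.43, -1.87 to -1.01), and Calr, an endoplasmic reticulum chaperone, 169 and 68.3 (-1.301, -1.91 to -0.70).

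The promoters ranked lowest with both antibodies past the stricter filter were those of Tm2d1, Fam222b, Sptan1, Ddx50, Hist1h4k, Slc9a8, Ifnar1, Cnn1, Whsc1l1 and Txnip. Txnip, a regulator of thioredoxin and glucose uptake, held 2259 and 364 (about 78 and 13 reads, log2 ratio -2.63, -3.56 to -1.73). Sptan1, the alpha chain of spectrin, held 828 and 184 (-2.17, -3.83 to -0.98), and Cnn1, the smooth muscle protein calponin, 906 and 244 (-1.89, -3.29 to -0.80). Actin and SRF targets were the only list apart from the mitochondrial and receptor genes outside the central 95% of random lists (21 of 25 measured members lower, median -1.42 against -1.07, percentile 1.09, but 11.02 matched on gene length). Tagln, an actin-binding protein of smooth muscle, held 1455 and 429 (-1.76). Those ranked highest included Bcl9, Atxn7l2, Ednra, Dgka, Fbxl19, Kif2c, Ccdc136, Ttl and Pnrc1. Bcl9, a Wnt pathway cofactor, held 62.7 and 145, worth about 2 and 5 reads (1.199, -1.29 to 4.71), and for each of these genes the counting interval held 0, so an increase was not detectable at this depth.

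Over all 14423 promoters measured with total Pol II the median log2 ratio was -1.07 (quartiles -1.92 and -0.41), with 9986 at least 1.5-fold lower and 1067 higher. Over 13878 gene bodies it was -0.56 (quartiles -0.93 and -0.20), with 6604 lower and 1119 higher. Simulated bodies with a common log2 change of -1 and more background gave -0.56 with total Pol II and -0.65 with Ser5P, so gene body medians can understate a common change. Without a filter the balance was different, with 13074 lower and 6504 higher at promoters (median -0.77) and 8497 and 7710 over bodies (-0.0089). The filter asks for less in SCR than in shRPAP1 (signal above 29.57 against 58.42 at promoters and 25.84 against 36.88 over bodies), so it admits genes high in SCR more easily. The medians also depend on the scaling of the libraries, which the sources do not state: with background genes set equal they were -1.86 and -1.35 (12762 promoters lower and 607 higher, 12228 bodies lower and 674 higher), and with the median of ratios set to 1 the counts were 4408 lower and 3911 higher at promoters and 2213 and 2115 over bodies. Lists are therefore described relative to genes of like signal, which a scaling does not change.

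**Figure D1:**
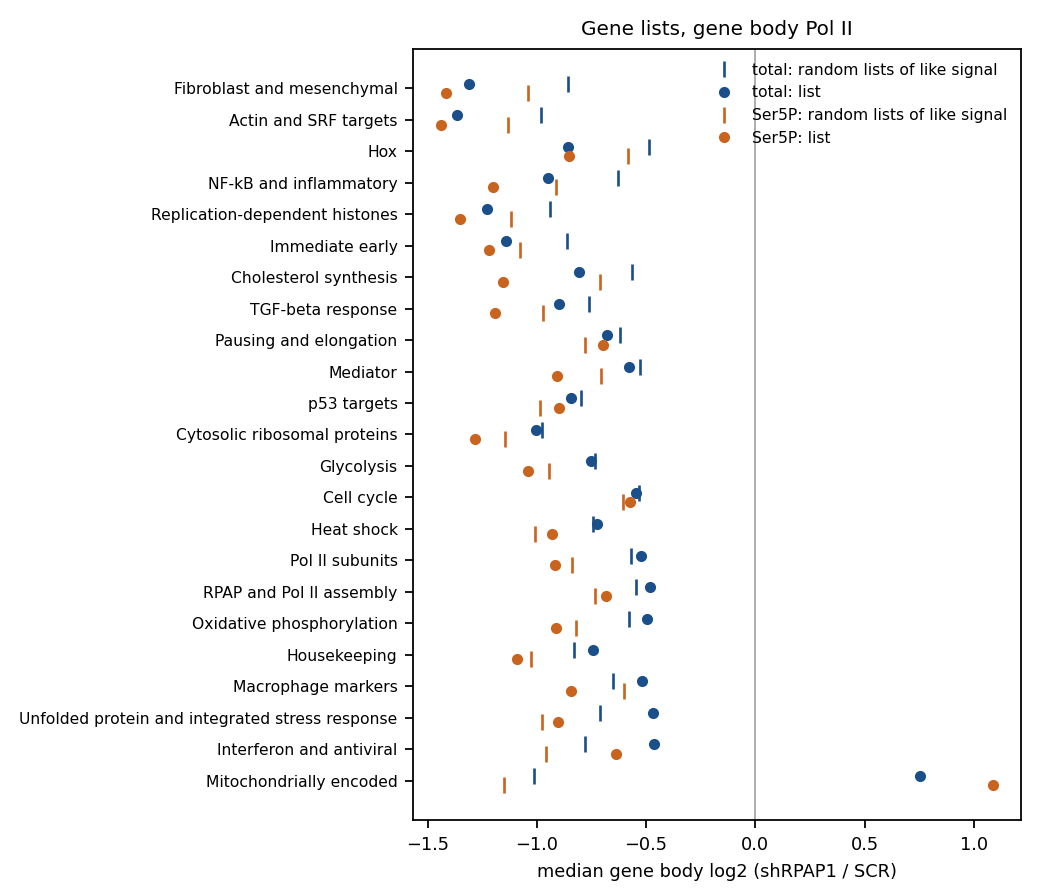
Median gene body log2 ratio of shRPAP1 over SCR for gene lists with at least 5 measured members with each antibody, olfactory and vomeronasal receptors left out (circles), and for random lists of like signal (vertical bars), in total Pol II (blue) and Ser5P (orange), 1 library per group. Fibroblast genes lie at -1.31 and -1.42 and actin and SRF targets at -1.37 and -1.44, left of their random lists, while the mitochondrially encoded genes lie at 0.75 and 1.09; with background genes set equal the total Pol II median of the latter was -0.047.

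Ser5P Pol II as deposited was likewise lower at most measured genes in the shRPAP1 library. In the most occupied decile, ranked by total Pol II in SCR, it was 2.19-fold lower over gene bodies (median log2 ratio -1.13, 1725 genes) and 2.04-fold lower at promoters (-1.03, 1704 genes). Tnc held 615 over its body in SCR and 120 in shRPAP1 (5.10-fold lower, log2 ratio -2.35, -2.45 to -2.26). The other gene bodies ranked lowest with both antibodies were those of Hist1h2ao, Timp1, Lbh, Cdc42ep3, Tpm1, Hist1h4c, Wisp1, Slc20a1 and Plau. Plau, the urokinase plasminogen activator, held 617 and 171 in Ser5P (-1.85, -2.15 to -1.55). Wisp1, a secreted matrix-associated protein, held 593 and 149 (-1.99, -2.14 to -1.85). Slc20a1, a phosphate transporter, held 700.5 and 181 (-1.95, -2.16 to -1.75), and Cdc42ep3, an effector of the GTPase Cdc42, 371 and 92.2 (-2.01, -2.23 to -1.79).

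Over gene bodies 34 of 37 measured fibroblast and mesenchymal genes were at least 1.5-fold lower in Ser5P (median -1.42 against -1.04, percentile 0), as were 26 of 27 actin and SRF targets (-1.44 against -1.13, percentile 0.15). Timp1 held 577 and 139 (-2.05, -2.45 to -1.64) and Actg2 354 and 82.6 (-2.10, -2.33 to -1.88). Genes of cholesterol synthesis had 21 of 22 members at least 1.5-fold lower in Ser5P (median -1.16 against -0.71, percentile 0), and with total Pol II 13 of 16 (-0.81 against -0.56, percentile 3.13, but 0.59 without a filter). All 78 cytosolic ribosomal protein genes were at least 1.5-fold lower in Ser5P over the body (median -1.28 against -1.15, percentile 0.52). Rpl27a held 674 and 207 (-1.70, -2.13 to -1.297). With total Pol II 72 of the 78 were (-1.002 against -0.97, percentile 32.6, but 0.080 matched on gene length).

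NF-kB and inflammatory genes were lower in Ser5P than genes of like signal over bodies (18 of 21, median -1.20 against -0.91, percentile 0.85, but 12.6 past the stricter filter) and at promoters (18 of 21, with 2 higher, -1.51 against -0.98, percentile 0.23). Over its body Ccl2 held 763 and 84.5 (-3.17, -4.11 to -2.41), the largest difference in the list. Its promoter-lowest member Relb, a subunit of NF-kB, held 506 and 4.33. Histone genes had 63 of 70 bodies lower and 2 higher (median -1.35 against -1.12, percentile 0.010) and 66 of 68 promoters lower (-1.17 against -1.03, percentile 1.32, but 7.30 matched on gene length). Hox bodies lay at the 0.60th percentile (22 of 32 lower, -0.85 against -0.58), but at the 56.2nd matched on gene length. Immediate early genes lay at the 7.30th percentile (23 of 27 lower, -1.22 against -1.08), but at the 0.35th matched on gene length. Nr4a1 held 469 and 156 (-1.59, -1.77 to -1.41).

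Interferon and antiviral genes again differed less than genes of like signal in Ser5P. At promoters 16 of 31 members were at least 1.5-fold lower and 3 higher (median -0.60 against -1.01, percentile 99.99), and over bodies 15 of 29 were lower and 0 higher (-0.64 against -0.96, percentile 99.8, but 86.4 matched on gene length and 72.9 past the stricter filter). With the median of ratios set to 1 their medians lay above 0, at 0.37 and 0.073. Rsad2 held 103 and 139 over its body (0.44, 0.12 to 0.75, but -0.34 with background genes set equal). Cxcl10, an interferon-induced chemokine, held 58.4 and 237 at its promoter (2.004) but 103 in each library over its body. Its promoter signal in SCR was worth only about 2 reads, so the counting error of that ratio is large. Chac1 held 224 and 295 over its body (0.39, -0.06 to 0.89), Hmox1, which degrades heme, 336 and 355 (0.08, -0.18 to 0.34), and Lgals3, a galectin, 105 and 110 (0.07, -0.29 to 0.41). With background genes set equal the Ser5P ratios of Chac1, Hmox1 and Lgals3 were -0.38, -0.70 and -0.71. Other bodies ranked highest with both antibodies were Yam1, Speer7-ps1, Sfi1, Rhox2e, Gmcl1l and Prl2c3. Sfi1, a centrosomal protein gene, held 141 and 214 in Ser5P (0.60, 0.49 to 0.71) and 132 and 237 in total Pol II (0.85, 0.74 to 0.96), but its Ser5P ratio was -0.18 with background genes set equal. With total Pol II the log2 ratio of the mean body signal of the background genes was 0.80, within the interval of Sfi1. A gain of Sfi1 beyond the background was therefore not shown.

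Over all 17045 promoters measured with Ser5P the median log2 ratio was -0.97 (quartiles -1.54 and -0.41), with 11759 at least 1.5-fold lower and 1934 higher. Over 17258 gene bodies it was -0.71 (quartiles -1.08 and -0.30), with 10097 lower and 1521 higher. Without a filter 14551 were lower and 5700 higher at promoters (median -0.87), and 11707 and 7581 over bodies (-0.25). With background genes set equal the medians were -1.57 and -1.48 (14341 promoters lower and 1245 higher, 15216 bodies lower and 782 higher), and with the median of ratios set to 1 the counts were 4084 lower and 4145 higher at promoters and 2757 and 3241 over bodies.

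**Figure D2:**
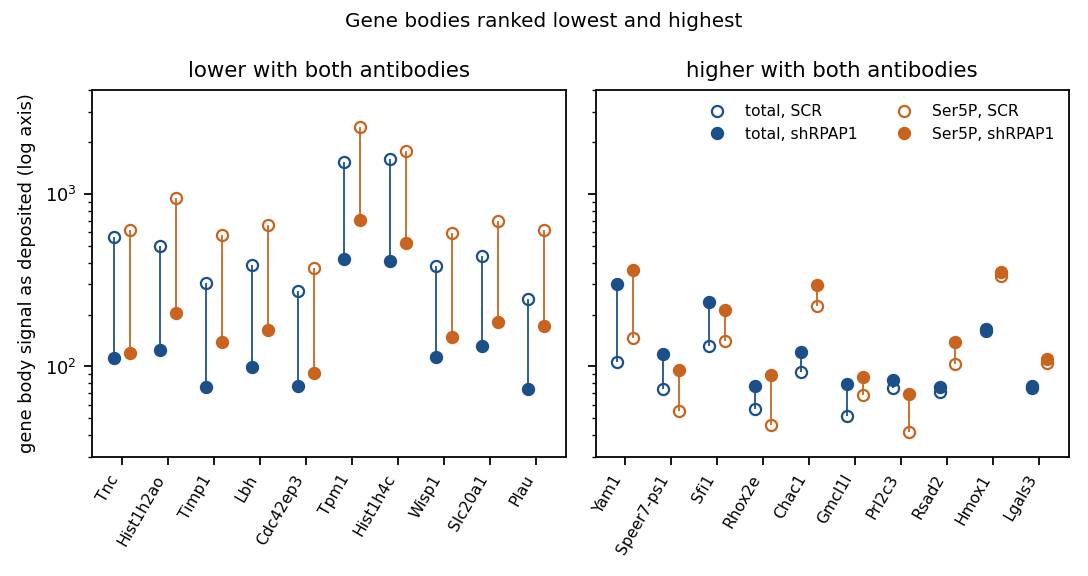
Gene body signal as deposited (log axis) of the 10 genes ranked lowest and the 10 ranked highest with both antibodies past the stricter filter, in SCR (open circles) and shRPAP1 (filled circles), for total Pol II (blue) and Ser5P (orange). Each point is 1 library; Tnc lies at 564 and 111 in total Pol II and at 615 and 120 in Ser5P.

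The 13 mitochondrially encoded genes, which Pol II does not transcribe, had more signal in the shRPAP1 libraries as deposited. Their median promoter signal was 2097 in SCR and 4019 in shRPAP1 with total Pol II (log2 ratio 0.89, 11 of 13 at least 1.5-fold higher), and 1870 and 4014 with Ser5P (1.11, 13 of 13), but with background genes set equal these ratios were 0.086 and 0.50. Over gene bodies the median log2 ratios were 0.75 and 1.09, but -0.047 with total Pol II when background genes were set equal. The body of mt-Atp6, a subunit of the ATP synthase, held 1458 and 3535 with total Pol II. Measured olfactory and vomeronasal receptor genes had gene body medians of 0.37 with total Pol II (72 of 156 higher, 51 lower; -0.42 with background genes set equal) and 0.80 with Ser5P (80 of 149 higher, 54 lower; 0.024 with background genes set equal), and promoter medians of -0.43 (36 of 106 higher, 48 lower; 0.64 with the median of ratios set to 1) and 1.86 (80 of 130 higher, 43 lower). These genes set the filter, so the measured ones are those that were high in a library, and their percentiles of 100 carry no weight (74.0 for total Pol II at promoters with the mean background subtracted and lists matched on the other antibody). Vmn1r129 had no body coverage in either SCR library and 46.3 and 66.6 in shRPAP1.

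Lists of transcription machinery genes lay within the central 95% of random lists of like signal over gene bodies, the Mediator list in Ser5P near the edge. Among 18 RPAP and Pol II assembly genes 5 of 12 measured were at least 1.5-fold lower with total Pol II and 10 of 17 with Ser5P (percentiles 65.3 and 64.1). Hsp90ab1, a chaperone, held 295 and 154 with total Pol II (-0.93, -1.32 to -0.55), and Gpn3, a GTPase of Pol II assembly, 26.5 and 26.7 (0.01, -0.79 to 0.79). Pol II subunit genes had 6 of 12 and 13 of 13 lower (percentiles 61.0 and 29.5). The promoter of Polr2a, the largest subunit, held 3068 and 1274 with total Pol II (-1.27). Mediator genes had 11 of 24 and 21 of 28 lower (percentiles 31.6 and 2.72), and pausing and elongation genes 20 of 31 and 21 of 33 (percentiles 27.1 and 81.5, but 1.885 with total Pol II matched on gene length). Paf1, of the elongation complex named after it, held 154 and 57.9 with total Pol II (-1.41, -2.002 to -0.87), and Aff1, a super elongation complex scaffold, 95.1 and 45.1 (-1.07, -1.199 to -0.95).

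Most metabolic, proliferation and stress lists also lay within the central 95% of random lists over gene bodies, given here for total Pol II and then Ser5P. Glycolysis genes had 10 of 15 and 16 of 18 measured members at least 1.5-fold lower (percentiles 45.6 and 22.0). Oxidative phosphorylation genes had 16 of 38 and 34 of 44 (83.0 and 12.9), cell cycle genes 8 of 18 and 15 of 32 (45.7 and 61.3), and housekeeping genes 20 of 27 and 25 of 27 (76.7 and 24.9). p53 targets had 17 of 22 and 20 of 25 (36.1 and 79.4), heat shock genes 9 of 17 and 15 of 18 (55.8 and 75.2), and TGF-beta response genes 15 of 19 and 17 of 19 (15.8 and 3.15). Stress response genes had 19 of 24 with Ser5P (74.8). Several of these lists entered the tails with lists matched on gene length: TGF-beta response genes at 0.10 and 0, p53 targets at 1.68 with total Pol II, and, with Ser5P, housekeeping genes at 0.33, glycolysis genes at 0.40 and cell cycle genes at 98.3. The random lists there were matched on length in place of signal, so such shifts cannot be put down to length. With the mean background subtracted and lists matched on the other antibody, oxidative phosphorylation genes lay at 99.2 with total Pol II. Tgfb3, a TGF-beta ligand, held 617 and 149 in Ser5P (-2.05, -2.22 to -1.89), Mcm7, a subunit of the replicative helicase, 186 and 94.9 (-0.97, -1.38 to -0.55), and Cryab, a small heat shock protein, 255 and 86.0 (-1.57, -1.92 to -1.23). Phlda3, a p53 target, held 554 and 201 (-1.46, -1.91 to -1.02).

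Among markers of other cell types, those of macrophages were measured most often, with 8 of 19 gene bodies with total Pol II, 14 of 19 with Ser5P and 15 of 19 promoters with Ser5P. At least 1.5-fold lower were 3 of the 8 bodies with total Pol II and 9 of the 14 with Ser5P, with 1 higher (percentiles 72.8 and 11.2, but 0.59 with total Pol II without a filter). Cd68, a lysosomal protein of macrophages, held 260 and 108 with total Pol II (-1.26, -2.13 to -0.48). Pluripotency genes had too few measured bodies for a percentile with total Pol II and lay at the 85.9th with Ser5P (2 of 5 lower, 1 higher), and epithelial genes at the 52.7th (3 of 8 lower; the 1.94th without a filter). Endothelial, skeletal muscle and neural markers and the genes of other silent tissues had fewer than 5 measured bodies with either antibody. Syn1, a synaptic vesicle protein, was among the measured neural markers, at 82.4 and 34.01 with total Pol II (-1.27, -1.51 to -1.05).

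At promoters, the other lists lay within the central 95% of random lists with each antibody, where a percentile was given. The closest to its edges were interferon genes with total Pol II (17 of 29 lower, median -0.76 against -1.06, percentile 96.7) and cholesterol synthesis genes with Ser5P (20 of 22 lower, -1.32 against -1.01, percentile 2.69). Both entered the tails with the mean background subtracted and lists matched on the other antibody (99.1 and 0.78), as did NF-kB and inflammatory genes with total Pol II (1.755). Msmo1, a sterol oxidase, held 625 and 169 in Ser5P (-1.88). Fibroblast genes lay at percentiles 9.54 and 13.2, with 30 of 35 and 31 of 39 measured promoters lower. Cdh11, a mesenchymal cadherin, held 375 and 58.4 with total Pol II (-2.67), and Dcn, the matrix proteoglycan decorin, 58.4 and 116 (0.98, with 87.3 in each Ser5P library). Across regions and antibodies, 27 of 103 list medians lay outside the central 95%, and 19 of 95 without the receptor and mitochondrial genes, where random lists alone would give 4.75. The same lists recur across regions and antibodies, and members of a list may vary together, which randomly drawn genes need not. The 4.75 is therefore no test of this count.

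The comparison of Ser5P with total Pol II asked whether the phosphorylated form moved more than all Pol II. The median difference of log2 ratios, Ser5P minus total, was 0.087 at 13118 promoters (quartiles -0.70 and 0.97) and -0.14 over 12712 gene bodies (quartiles -0.44 and 0.14). Ccl2 was among the genes with a lower Ser5P ratio over the body, at -3.17 against -1.92, and Pmaip1, a pro-apoptotic p53 target, at -1.68 against -0.83. Polr2c, a Pol II subunit gene, had a body ratio of -0.81 in Ser5P and 0.11 in total Pol II. The promoter of Txnip went the other way, at -1.84 in Ser5P and -2.63 in total Pol II. The sign was not stable: the median was -0.24 at promoters past the stricter filter and 0.20 over bodies with the median background subtracted.

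Promoter and gene body were compared to see whether Pol II changed in its distribution along genes. Promoter signal exceeded gene body signal by a median factor of 3.50 in SCR and 2.496 in shRPAP1 with total Pol II (10291 genes), and of 6.12 and 5.34 with Ser5P (13676 genes). The median difference of log2 ratios, promoter minus body, was -0.49 with total Pol II and -0.24 with Ser5P, but 0.10 and 0.0047 with the median background subtracted. With the median of ratios set to 1 in each region it was 0.025 and 0.016, near 0 by construction. Txnip and Cnn1 promoters and Tnc and Tpm1 bodies show that large differences were measured in each region. Past the stricter filter, which also selects on the shRPAP1 values, the difference was -0.063 with total Pol II (875 genes) and 0.035 with Ser5P (2375 genes). In the highest decile of promoters ranked by the SCR signal of the other antibody, without a filter, it was -0.43 with total Pol II and -0.17 with Ser5P (3618 genes each). This was nearer 0 than in deciles 8 and 9 (-0.65 and -0.63 with total Pol II, -0.40 and -0.33 with Ser5P). In decile 7 it was -0.34 and -0.30, and in decile 6, where promoters had a median of 0 reads in SCR, -0.071 and -0.079. Simulated Ser5P libraries with the same change in both regions gave -0.31 over measured genes and -0.25 in the highest decile, further from 0 than the measured values. Simulated body reads were not set to the measured read numbers, so these values are not a like benchmark. Fibroblast and actin genes stood apart from genes of like signal more over bodies (percentiles 0 to 0.15) than at promoters (1.09 to 20.9), a difference that was not tested.

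The ratios of the antibodies were related across gene bodies, and only weakly at promoters, where reads were few. Over bodies measured with both, 5059 genes were at least 1.5-fold lower with both antibodies, where independent lists would share 3916, and 290 were higher with both, where independent lists would share 40.6. Of all measured bodies 1119 and 1521 were higher with total Pol II and Ser5P, but 256 and 418 over protein-coding genes. Lower were 6604 and 10097 of all, and 4456 and 7139 over protein-coding genes. Background was higher in both shRPAP1 libraries, so shared increases can reflect it. Pearson's r across 12712 bodies was 0.21 and Spearman's rho 0.45, and past the stricter filter they were 0.60 and 0.54 over 1340 genes. Simulated genes with no change of their own gave a rho of 0.23 past a filter of the same rule. That is not a like benchmark, since 3423 simulated genes passed and simulated body reads were not set to the measured read numbers. Tnc (-2.34 and -2.35), Lbh (-1.97 and -2.01) and Tpm1 (-1.86 and -1.80) had close ratios with total Pol II and Ser5P. At 13118 promoters Pearson's r was 0.081 and Spearman's rho 0.076, with 7009 lower with both against 6752 for independent lists. Measured promoters had a median of about 6 and 3 reads in SCR and shRPAP1 with total Pol II, against about 88 and 61 over bodies. Counting error lowers agreement more at so few reads, so the regions cannot be compared on this. Genes are not independent replicates, and both antibodies used chromatin of the same pooled design.

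Occupancy and gene length were examined to see which genes differed more. Over gene bodies the median total Pol II ratio went from 0.00 in the least occupied decile to -1.03 in the most occupied, and that of Ser5P from -0.67 to -1.13, with the smallest difference of -0.40 in the third decile. Background over bodies was 1.74 and 1.72 times higher in shRPAP1, which can draw weakly occupied bodies toward 0. Simulated total Pol II bodies with a common change gave -0.56 over measured genes and -0.87 in the most occupied decile. Most minus least occupied stayed at -1.09 and -0.55 with the median background subtracted, so a larger change at occupied genes cannot be told apart from background. At promoters the most and least occupied deciles had -1.12 and -1.07 with total Pol II, and -1.03 and -0.42 with Ser5P. The total Pol II difference between these deciles was -0.50 with the median background subtracted. It was -1.10 with the mean background subtracted and the stricter filter together, where the least occupied decile lay at -0.037. That filter also selects on the shRPAP1 values, so it leaves out weakly occupied promoters that fell, and the -1.10 cannot be read as a trend with occupancy. Short genes had larger differences over gene bodies: the medians in the shortest and longest quintiles were -0.72 and -0.47 with total Pol II and -0.97 and -0.51 with Ser5P. This order was not stable: longest minus shortest turned to -0.12 for total Pol II with the median background subtracted, and to -0.39 and -0.21 with the mean background subtracted and the stricter filter together. At promoters the quintiles differed little, with -1.04 and -1.19 for total Pol II and -0.97 in each for Ser5P.

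**Figure D3:**
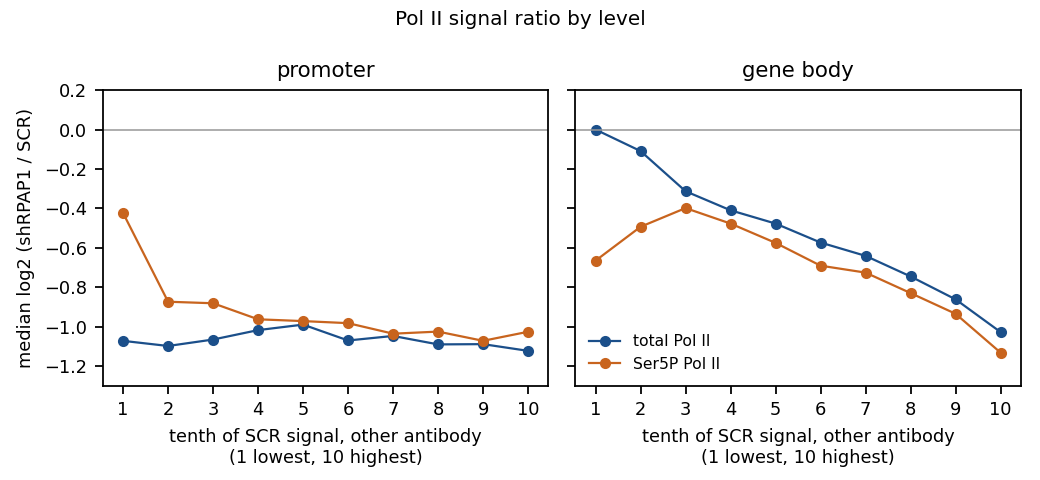
Median log2 ratio of shRPAP1 over SCR in deciles of genes ranked by the SCR signal of the other antibody, at promoters and over gene bodies, for total Pol II (blue) and Ser5P (orange), 1 library per group. The highest deciles lie at -1.12 and -1.03 at promoters and at -1.03 and -1.13 over gene bodies.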

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

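Among the tests below, those of fewer reads, of the yield of the immunoprecipitations, of a lower share of fibroblasts and of promoters with few reads were chosen after the result was seen.

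Rpap1 is listed because its promoter log2 ratios had opposite signs, 0.62 in total Pol II and -0.71 in Ser5P, both within counting error and with signs that depend on the scaling, and their difference was not tested. The 13 predicted Gm-number genes with the highest promoter signal also moved in opposite directions, as deposited, with median log2 ratios of -0.72 in total Pol II and 0.93 in Ser5P, again untested, but both lay above 0 with the median of ratios set to 1 (0.35 and 1.90). Mitochondrially encoded genes are listed because they carry signal outside the Pol II measurement, higher in shRPAP1 by a median log2 ratio of 0.89 in total Pol II and 1.11 in Ser5P at promoters, but 0.086 and 0.50 with background genes set equal.

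Pol II signal was lower at most measured genes in both shRPAP1 libraries. Fewer reads alone would lower background alike, but mean promoter signal of the background genes, most of them receptors, was at least 1.53 times higher in shRPAP1 with either antibody. This argues against fewer reads as the only source. The 39 other silent genes were 1.49 and 4.61 times higher at promoters but 1.08 and 1.06 times over bodies. Total read numbers are not given, so fewer reads together with a lower yield of the immunoprecipitations cannot be told apart. A larger share of background reads acting alike on genes of one level does not account for the differences between genes, since after the level was taken off the gene body ratios of the antibodies were related (Spearman's rho 0.35 over 1340 genes, and 0.31 without Gm-number and mitochondrial genes). A lower yield of the immunoprecipitations and less Pol II on genes cannot be told apart for the common shift, which was -1.03 over the most occupied decile of gene bodies with total Pol II, because the table has no spike-in or input values. The effect of RPAP1 depletion itself stays open as a biological explanation.

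Fibroblast and actin genes fell more over gene bodies than genes of like signal. A dependence of the ratio on level and background is argued against, since with the mean background subtracted and lists matched on the other antibody the highest of the 4 percentiles was 0.28. Gene length cannot be told apart. Lists matched on length gave a highest percentile of 0, but they were not matched on signal, on which the gene body ratio also depends. A lower share of fibroblasts in the shRPAP1 cultures cannot be told apart, since markers of other cell types lay at the 29.5th percentile with total Pol II (14 genes) and the 2.68th with Ser5P (32 genes), not raised but few. A candidate explanation is a larger loss of Pol II from these genes on RPAP1 depletion, which remains a hypothesis without replicates.

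Total Pol II fell more at promoters than over gene bodies as deposited. The median of ratios set to 1 in each region gave 0.025, but that setting brings the difference near 0 by construction and cannot check it. Promoters of few reads near the threshold cannot be told apart, in the last of several tests tried for them. Within the highest decile of promoters by Ser5P in SCR, the median difference of log2 ratios moved toward 0 from the promoters with fewest to those with most reads, by 0.14 in the lowest tertile of Ser5P gene body signal, with overlapping intervals, and by 0.47 and 0.45 in the other two, as few reads would have it. The promoter ratios themselves changed by -0.23, 0.022 and 0.085, where few reads as the cause would have them rise, and gene body ratios fell as reads rose. Background reads in gene bodies cannot be told apart: the difference was -0.19 with the mean background subtracted, between the bounds set, and 0.10 with the median background subtracted. Simulated libraries with the same change in both regions and more background gave -0.36 over measured genes and -0.34 in that decile, where the measured value was -0.43 (interval -0.46 to -0.40). They are not a like benchmark, since simulated body reads were not set to the measured read numbers. Their background was 1.6 times higher, against 1.74 times over the measured background gene bodies with total Pol II. A change of Pol II distribution on RPAP1 depletion stays open and was not tested.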

How the results depend on the processing

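Some settings were added later: those given as chosen after seeing the data, the lists past the stricter filter, and the lists with the mean background subtracted and matched on the other antibody. The others were planned. Each median log2 ratio stayed below 0 under every setting run except the median of ratios set to 1, which fixes it at 0. The causes of the changes below were not tested. With the median of ratios set to 1, median log2 ratios were 0 (total promoters), 0 (Ser5P promoters), 0 (total bodies) and 0 (Ser5P bodies), and at least 1.5-fold lower were 4408 (total promoters), 4084 (Ser5P promoters), 2213 (total bodies) and 2757 (Ser5P bodies). At least 1.5-fold higher were 3911 (total promoters), 4145 (Ser5P promoters), 2115 (total bodies) and 3241 (Ser5P bodies), Ser5P minus total was -0.018 (promoters) and 0.010 (bodies), and promoter minus body, with a factor set for each region, was 0.025 (total) and 0.016 (Ser5P). This setting brings both of these differences near 0 by construction. Among named genes at least 1.5-fold changed as deposited, the sign turned for Rpap1, to 0.25 (Ser5P, promoter), and below that size also for its body, to 0.37 (Ser5P). With the background genes set equal, median log2 ratios were -1.86 (total promoters), -1.57 (Ser5P promoters), -1.35 (total bodies) and -1.48 (Ser5P bodies), and at least 1.5-fold lower were 12228 (total bodies) and 15216 (Ser5P bodies). At least 1.5-fold higher were 607 (total promoters), 1245 (Ser5P promoters), 674 (total bodies) and 782 (Ser5P bodies), Ser5P minus total was 0.27 (promoters) and -0.12 (bodies), and promoter minus body was -0.074 (Ser5P). Named genes at least 1.5-fold changed as deposited whose sign turned were Ednra -0.13 (total, promoter), Ccdc136 -0.17 (total, promoter), Speer7-ps1 -0.13 (total, gene body), Sfi1 -0.18 (Ser5P, gene body), Gmcl1l -0.19 (total, gene body), Prl2c3 -0.036 (Ser5P, gene body) and Rpap1 -0.18 (total, promoter), and smaller ratios above 0 turned too, among them Atxn7l2 -0.27 and Fbxl19 -0.46 (total, promoter), Ednra -0.24 and Dgka -0.25 (Ser5P, promoter), and Chac1 -0.38 and Hmox1 -0.70 (Ser5P, gene body). With the median background subtracted, median log2 ratios were -0.98 (total promoters), -1.10 (total bodies) and -0.95 (Ser5P bodies), and at least 1.5-fold lower were 10474 (total bodies). At least 1.5-fold higher were 1103 (Ser5P promoters), and Ser5P minus total was 0.013 (promoters) and 0.20 (bodies). Promoter minus body was 0.10 (total) and 0.0047 (Ser5P), and highest minus lowest decile was -0.50 (total promoters) and -0.48 (Ser5P promoters). Longest minus shortest quintile was -0.12 (total bodies) and 0.16 (Ser5P bodies). With a pseudocount 10 times smaller, the median log2 ratio was -0.98 (Ser5P promoters). With a pseudocount 10 times larger, median log2 ratios were -1.02 (total promoters), -0.94 (Ser5P promoters), -0.52 (total bodies) and -0.66 (Ser5P bodies), and Ser5P minus total was 0.058 (promoters). Without a filter, median log2 ratios were -0.77 (total promoters), -0.87 (Ser5P promoters), -0.0089 (total bodies) and -0.25 (Ser5P bodies), and at least 1.5-fold higher were 6504 (total promoters), 5700 (Ser5P promoters), 7710 (total bodies) and 7581 (Ser5P bodies). Ser5P minus total was 0 (promoters) and -0.12 (bodies), and promoter minus body was -0.42 (total). Past the stricter filter, median log2 ratios were -0.76 (total promoters), -0.95 (Ser5P promoters), -0.81 (total bodies) and -0.97 (Ser5P bodies), and at least 1.5-fold lower were 3014 (total promoters), 996 (total bodies) and 2407 (Ser5P bodies). At least 1.5-fold higher were 222 (total promoters), 256 (Ser5P promoters), 76 (total bodies) and 136 (Ser5P bodies), and Ser5P minus total was -0.24 (promoters). Promoter minus body was -0.063 (total) and 0.035 (Ser5P), and Spearman's rho was 0.14 (promoters) and 0.54 (bodies). Without predicted names, median log2 ratios were -1.09 (total promoters), -0.98 (Ser5P promoters), -0.57 (total bodies) and -0.73 (Ser5P bodies), and at least 1.5-fold higher were 680 (total promoters), 1086 (Ser5P promoters), 390 (total bodies) and 532 (Ser5P bodies). Ser5P minus total was -0.16 (bodies), and promoter minus body was -0.52 (total). With the mean background subtracted (chosen after seeing the data), median log2 ratios were -1.15 (total promoters), -1.02 (Ser5P promoters), -0.94 (total bodies) and -1.04 (Ser5P bodies), and at least 1.5-fold higher were 1062 (Ser5P promoters), 596 (total bodies) and 1001 (Ser5P bodies). Ser5P minus total was -0.034 (bodies), and promoter minus body was -0.19 (total) and 0.033 (Ser5P). With the mean background subtracted and the stricter filter together (chosen after seeing the data), median log2 ratios were -0.82 (total promoters), -0.98 (Ser5P promoters), -0.94 (total bodies) and -1.08 (Ser5P bodies), and at least 1.5-fold lower were 3166 (total promoters), 1098 (total bodies) and 2517 (Ser5P bodies). At least 1.5-fold higher were 215 (total promoters), 255 (Ser5P promoters), 73 (total bodies) and 135 (Ser5P bodies), and Ser5P minus total was -0.20 (promoters) and -0.11 (bodies). Promoter minus body was -0.011 (total) and 0.12 (Ser5P), and highest minus lowest decile was -1.10 (total promoters), -1.13 (total bodies) and -0.86 (Ser5P bodies). Longest minus shortest quintile was 0.091 (total promoters), -0.39 (total bodies) and -0.21 (Ser5P bodies). Over protein-coding genes (chosen after seeing the data), median log2 ratios were -1.10 (total promoters), -0.99 (Ser5P promoters) and -0.72 (Ser5P bodies), and at least 1.5-fold higher were 599 (total promoters), 911 (Ser5P promoters), 256 (total bodies) and 418 (Ser5P bodies). Ser5P minus total was -0.16 (bodies), and promoter minus body was -0.54 (total). Ranked by the SCR library of the same antibody, highest minus lowest decile was -1.93 (total promoters), -5.16 (Ser5P promoters), -2.23 (total bodies) and -2.26 (Ser5P bodies). Lists matched on gene length were not matched on signal, so changes of percentile under this setting can come from signal as well as length. Matched on gene length, list percentiles that left the tails were 11.02 (Actin and SRF targets, total promoters), 7.30 (Replication-dependent histones, Ser5P promoters), 85.8 (Interferon and antiviral, total bodies), 11.6 (Hox, total bodies), 86.4 (Interferon and antiviral, Ser5P bodies) and 56.2 (Hox, Ser5P bodies). With the mean background subtracted and lists matched on the other antibody, list percentiles that left the tails were 3.21 (Actin and SRF targets, total promoters), 74.0 (Olfactory and vomeronasal receptors, total promoters), 2.73 (Replication-dependent histones, Ser5P promoters), 15.5 (Immediate early, total bodies), 12.7 (Replication-dependent histones, total bodies), 95.2 (Interferon and antiviral, Ser5P bodies) and 4.71 (Hox, Ser5P bodies). Past the stricter filter, list percentiles that left the tails were 21.8 (Immediate early, total bodies), 92.1 (Interferon and antiviral, total bodies), 4.69 (Replication-dependent histones, total bodies), 72.9 (Interferon and antiviral, Ser5P bodies) and 12.6 (NF-kB and inflammatory, Ser5P bodies). List percentiles outside the tails that entered them were, matched on gene length, 2.41 (Epithelial, Ser5P promoters), 0.070 (Endothelial markers, Ser5P promoters), 1.885 (Pausing and elongation, total bodies), 0.10 and 0 (TGF-beta response, total and Ser5P bodies), 1.68 (p53 targets, total bodies), 0.080 (Cytosolic ribosomal proteins, total bodies), 1.90 (Cholesterol synthesis, total bodies), 0.35 (Immediate early, Ser5P bodies), 98.3 (Cell cycle, Ser5P bodies), 0.33 (Housekeeping, Ser5P bodies) and 0.40 (Glycolysis, Ser5P bodies). Without a filter they were 0.050 (Pluripotency, Ser5P promoters), 2.265 (Neural markers, Ser5P promoters), 1.33 (Cytosolic ribosomal proteins, total bodies), 0.59 (Cholesterol synthesis, total bodies), 0.59 (Macrophage markers, total bodies) and 1.94 (Epithelial, Ser5P bodies). With the mean background subtracted and lists matched on the other antibody they were 99.1 (Interferon and antiviral, total promoters), 1.755 (NF-kB and inflammatory, total promoters), 0.78 (Cholesterol synthesis, Ser5P promoters), 99.2 (Oxidative phosphorylation, total bodies), 0.55 (Cholesterol synthesis, total bodies) and 98.9 (Unfolded protein and integrated stress response, total bodies), and past the stricter filter 98.3 (Oxidative phosphorylation, total promoters), 1.345 (NF-kB and inflammatory, total promoters) and 0.97 (Cholesterol synthesis, Ser5P promoters). Of the 27 list medians in the tails, 27 stayed there with background genes set equal and 27 without a filter. Setting background genes equal shifts all ratios of a library pair nearly alike, so its result was close to fixed in advance and is no check. Not run were TMM (the values are not counts), no scaling (values were used as deposited), input subtraction (no input column) and all RNA-seq alternatives. No paired analysis was possible because the ChIP-seq data have 1 library per group, and the RNA-seq samples whose labels share replicate numbers have no values in the table. Depth limits promoters most: measured promoters had a median of about 6 reads in SCR and 3 in shRPAP1 with total Pol II, and 11 and 6 with Ser5P.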

Other observations

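The gene families and the genes named in this part were chosen after values had been seen. Collagen genes were lower over gene bodies than genes of like signal: 12 of 15 measured members were at least 1.5-fold lower with total Pol II (median log2 ratio -1.29 against -0.80, percentile 0.36) and 17 of 21 with Ser5P (-1.42 against -0.76, percentile 0). Of these, 7 and 8 also belong to a fixed list, and the 8 and 13 others had medians of -1.37 (percentile 0.35) and -1.11 (percentile 0.41). Col5a1 held 248 in SCR and 78.5 in shRPAP1 with total Pol II (-1.65) and Col4a1, a basement membrane collagen, 145 and 46.0 (-1.65). Myosin light chains and tropomyosins had 8 of 9 and 9 of 10 members lower (medians -1.31 and -1.47, percentiles 2.82 and 0.84), of which 4 with each antibody belong to a fixed list, and without them the percentiles were 2.88 and 4.68. Myl9, a regulatory light chain of contractile myosin, held 611 and 177 in Ser5P (-1.78). Integrin genes were lower than genes of like signal at Ser5P promoters (15 of 19, median -1.58 against -0.97, percentile 0.55), but lay among them with total Pol II (12 of 15 lower, -1.11 against -1.03, percentile 41.8), and did not stand apart as a family over gene bodies (percentiles 50.4 and 54.0), although Itgb1, the beta subunit shared by many integrins, held 443 and 148 with total Pol II (-1.58) and Itga5, its fibronectin-binding partner, 452 and 142 (-1.67). With the median of ratios set to 1 the integrin gene body median in Ser5P was 0.044.

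Chemokine bodies had 8 of 14 measured members at least 1.5-fold lower and 1 higher with total Pol II (median -0.82 against -0.49, percentile 2.16) and 13 of 18 with Ser5P (-1.19 against -0.76, percentile 0.39). Of these, 6 and 8 belong to the fixed lists, and without them the percentiles were 13.5 and 12.2. At promoters the family lay at percentile 0.88 with total Pol II (9 of 11 lower) and 8.225 with Ser5P (11 of 15 lower and 3 higher), and outside the fixed lists at 0.74 and 13.03, but several of the total Pol II promoters had no coverage in shRPAP1, where a ratio has no meaning. Ccl7, which attracts monocytes, held 1058 and 194 in Ser5P (-2.44). Zinc finger protein genes of the Zfp series differed slightly less than genes of like signal over gene bodies with total Pol II (79 of 246 lower and 3 higher, median -0.43 against -0.51, percentile 98.7). Their median there was 0.13 with the median of ratios set to 1. They did not stand apart over bodies with Ser5P (percentile 83.6) or at promoters (47.65 with total Pol II and 35.8 with Ser5P). Proteasome, tRNA synthetase, chaperonin, splicing factor and tubulin genes lay within the central 95% of random lists over gene bodies with both antibodies. Hosts of small nucleolar RNAs had 9 of 9 and 8 of 9 bodies lower (percentiles 17.6 and 4.92). Snhg1 held 790 and 340 with total Pol II (-1.21).

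The background genes were not alike. Mean gene body signal was 1.76 times higher in shRPAP1 than in SCR over the 1760 receptor genes with total Pol II and 1.74 times with Ser5P, but 1.08 and 1.06 times over the 39 other silent genes. At promoters the receptor genes were 1.75 and 1.51 times higher and the 39 other genes 1.49 and 4.61 times. The 13 Gm-number genes with the highest signal had median promoter values of 11150 in SCR and 6843 in shRPAP1 with total Pol II, and 7091 and 13487 with Ser5P.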
